A study of Mus musculus with 36 samples.

How the data were processed

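The deposited data were 1 scanner file for each of 36 2-colour Agilent arrays and 1 series matrix. Per the labels, each sample's RNA was labelled with Cy3 and the common reference with Cy5, with no dye swap, so a dye effect is not balanced within a group but is shared by the groups compared. Tamoxifen was given at 200 nM and doxycycline at 1.5 µg/ml per the labels' protocols; the protocols of the wild MEFs labelled as treated, and of replicate 2 of the day 1 cultures labelled with tamoxifen alone, mention no tamoxifen. Groups were taken from the labels.

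Spots were quantified with Agilent Feature Extraction 9.5.1.1, per the file headers. The deposited values used were the mean intensity of each spot and the median intensity of its local background in both channels, which are not normalized. The log10 ratio that Feature Extraction writes was used as an alternative; per the file headers it is red over green after that software's own background model and dye normalization, so its sign was turned. The series matrix was used as another alternative. Its deposited values, for 25030 probes, had medians between 2.37 and 2.46 per array and correlated at 0.989 to 0.996 with log10 of the sample channel, so they were read as log10 sample brightness. The adjustment and any centring made to them are not given in the sources used here.

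Each file held 43451 spots, 42034 of them not controls, for 42006 probes of 60 bases. The gene name column repeated the probe identifier for every probe and no description or position was given. The table of RefSeq symbols could not be joined to these identifiers. The gene lists fixed beforehand, and the rule to name up to 10 rising and 10 falling genes by symbol, could therefore not be applied. In their place the text names at most 2 rising and 2 falling probes per comparison, those with the largest change among called probes whose groups did not overlap, and their values in other comparisons.

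Background was corrected with limma's normexp method with an offset of 50, and log ratios were normalized by loess within each array, with control spots and spots marked as non-uniform given no weight. Spots of 1 probe were averaged. Ratios are sample over reference. Probes had to be well above background in the sample channel on both arrays of at least 1 group, which kept 33099 and removed 8907. Limma's lmFit was run on all 36 arrays with 1 mean per group (18 residual and 3.07 prior degrees of freedom), followed by contrasts and eBayes, two-sided, with Benjamini-Hochberg adjustment within each contrast and calls at an adjusted p under 0.05. Sets were tested with limma's camera, with a preset correlation of 0.01 and with an estimated one, adjusted over the 2 planned sets. These choices were made before the data were examined, except for the comparisons of day 6 with day 3 and 3 further sets of probes. Pairing by replicate number was checked, and no consistent pairing was found.

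The planned background correction failed on 2 arrays. In wild MEFs with tamoxifen replicate 1, 6 spots had local backgrounds far above their signal (lowest difference -34169), and normexp's noise estimate was 446 and 566 in the 2 channels. In secondary MEFs of day 6 with neither drug replicate 1 the estimate for the reference channel was 171. The other 34 arrays had a median of 0.873 and none above 8.91. All comparisons share 1 estimate of the spread per probe, so the 2 faulty arrays can widen the SE of comparisons that do not use them. The planned values stayed the main ones, and 3 alternatives were added after seeing the data: local backgrounds that Feature Extraction marks as outliers replaced by the array's median on all 36 arrays, normexp by maximum likelihood, and a fit without the 2 arrays. The other alternatives had been chosen beforehand: no background subtraction, Feature Extraction's ratio, no filter on dim probes, the series matrix, only the arrays of the same experiment, replicate number as a block, slide as a random block, an estimated set correlation, and each replicate left out in turn. The fit with slide as a block held only the secondary MEF arrays and took each drug effect as equal on all days.

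The fit was tested on simulated data with 32917 probes, drawn with independent normal noise of the fitted spread and the same changes on every day. For tamoxifen with doxycycline on day 6, 73 of 100 probes changed by 0.5 and 97 of 100 changed by 1 on the log2 scale were recovered, with 15 false calls. For the interaction 87 and 99 of 100 were recovered, with 8 false calls, and a comparison simulated without change gave 0 calls. The simulation held no deviation shared by the probes of an array or the arrays of a slide. It therefore does not check the rate of false calls in the real data. The arrays came from 11 slides and 5 scan days. R 4.3.3 and limma 3.58.1 were used.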

Results

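RNA of mouse cells was measured on 36 2-colour arrays in 18 groups of 2. Each array carried a sample in Cy3 against 1 common reference in Cy5, a pool of RNA from mouse cell lines mixed with embryonic stem (ES) cell RNA. The groups were primary mouse embryonic fibroblasts (MEFs), either wild or carrying a Zscan4ERT2 transgene, with and without tamoxifen; secondary MEFs labelled KOS-ZERT2, with and without doxycycline and tamoxifen on days 1, 3 and 6; induced pluripotent stem (iPS) cells; and ES cells. ERT2 is a receptor domain that tamoxifen compounds bind, and a protein fused to it becomes active in their presence. Doxycycline switches on inducible transgenes. The series title names the question, the role of Zscan4 in making iPS cells. Between 54.9% and 77.1% of probes were well above background in the sample channel of an array, and the number of arrays limits the precision. The labels do not say that the 2 samples of a group came from separate cultures, so p-values measure only the spread within groups, which can be technical. That spread is pooled over all 18 groups, so the 2 arrays whose background correction failed can lower the calls of every comparison. iPS against ES cells, which use neither array, had 1309 calls, and 2687 with outlying local backgrounds replaced. Probes are given by their identifiers, since no gene name was paired with them in the sources used here, so the levels of the Zscan4 and reprogramming factor transgenes were not checked.

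ES cells and untreated wild MEFs differed at most of the probes measured. Probe Z00034687-1 was 348-fold higher in ES cells (log2 fold change 8.44, SE 0.448, adjusted p = 9.54e-14) and Z00072411-1 was 261-fold higher. Probe Z00030484-1 was 998-fold lower in ES cells (log2 fold change -9.96, SE 0.134, adjusted p = 1.5e-24) and Z00075103-1 was 988-fold lower. Of 33098 probes tested, 10724 were higher and 12738 lower in ES cells at an adjusted p under 0.05 in limma. Of these, 1194 were at least 4-fold higher in ES cells (ES-high probes) and 2500 at least 4-fold higher in MEFs (MEF-high probes). The 2 sets come from arrays that no comparison of the secondary MEFs uses, and they serve here as markers of the ES and MEF states. The ES and wild MEF arrays lay on different slides scanned on different days, so a part contributed by slide to the counts stays open. Z00034687-1 had log2 ratios of -6.69 ± 0.11 (SD, n = 2) in wild MEFs, -6.63 ± 0.17 (SD, n = 2) in untreated Zscan4ERT2 MEFs and -7.12 ± 0.08 (SD, n = 2) in untreated secondary MEFs of day 3, on 3 slides, the last scanned on the same day as the ES cells, against 1.75 ± 0.06 (SD, n = 2) in ES cells.

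Doxycycline changed a large part of the measured transcripts of the secondary MEFs within 1 day. Probe Z00074466-1 rose by 6.73 on the log2 scale on day 1 (SE 0.171, adjusted p = 1.56e-18), 8.29 on day 3 and 7.41 on day 6. Its log2 ratio to the reference on day 6 was -2.76 ± 0.43 (SD, n = 2) without and 4.65 ± 0.05 (SD, n = 2) with doxycycline. Probe Z00035949-1, which was MEF-high, changed by -4.12 on day 1 (SE 0.081, adjusted p = 2.69e-20), -8.03 on day 3 and -8.12 on day 6. Some differences shrank with time: Z00025746-1 was higher by 6.09 on day 1, 3.42 on day 3 and 0.86 on day 6 (0.49 with outlying local backgrounds replaced), a difference between days 6 and 1 of -5.23 (SE 0.443, adjusted p = 3.54e-09). Its log2 ratio went from 1.42 ± 0.18 (SD, n = 2) on day 1 to 4.65 ± 0.59 (SD, n = 2) on day 6 without doxycycline, and from 7.51 ± 0.01 (SD, n = 2) to 5.51 ± 0.04 (SD, n = 2) with it. Without tamoxifen, 6755 probes rose and 6097 fell on day 1, 9259 rose and 7972 fell on day 3, and 8103 rose and 7549 fell on day 6. At least 2-fold changes were called for 1432 rising and 706 falling probes on day 1, 2662 and 1468 on day 3, and 2129 and 1693 on day 6. The effect differed between days 6 and 1 at 10629 probes.

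As sets, the ES-high probes were shifted upwards and the MEF-high probes downwards by doxycycline, with members called both ways. The median log2 change of the ES-high probes was 0.05 on day 1, 0.44 on day 3 and 0.24 on day 6, and 315, 600 and 517 of the 1194 rose while 102, 86 and 124 fell. Adjusted over the list alone, 310, 605 and 523 rose. The MEF-high probes had medians of -0.14, -0.44 and -0.55, with 973, 1376 and 1488 of 2500 falling and 581, 563 and 484 rising. Adjusted over the list alone, 1011, 1404 and 1518 fell. With a preset correlation between probes, limma's camera test gave adjusted p = 0.00713, 2.14e-09 and 4.01e-06 for the ES-high probes and 0.00526, 1.11e-09 and 1.25e-14 for the MEF-high probes on days 1, 3 and 6. With an estimated correlation none of these calls held (adjusted p = 0.726, 0.438 and 0.549 for ES-high, and 0.726, 0.429 and 0.246 for MEF-high probes). The planned background correction failed on 2 arrays. With outlying local backgrounds replaced the estimated correlation of the ES-high probes was 0.066 in place of 0.619, and their median on day 6 was 0.40. The calls of days 3 and 6 then held with an estimated correlation while those of day 1 did not (adjusted p = 0.277 for both sets). Cultures with and without doxycycline lay on different slides on each day, so slide and doxycycline cannot be told apart within a day. Across days, on other slides, 11885 of the 12266 probes called on days 3 and 6 had the same direction on both. Independent lists would share 4084.9 in the same direction, but both lists use 1 estimate of the spread per probe, which raises their overlap. With slide as a random block and each drug effect taken as equal on all days, 12053 probes were called for doxycycline averaged over days in place of 20043.

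**Figure D1:**
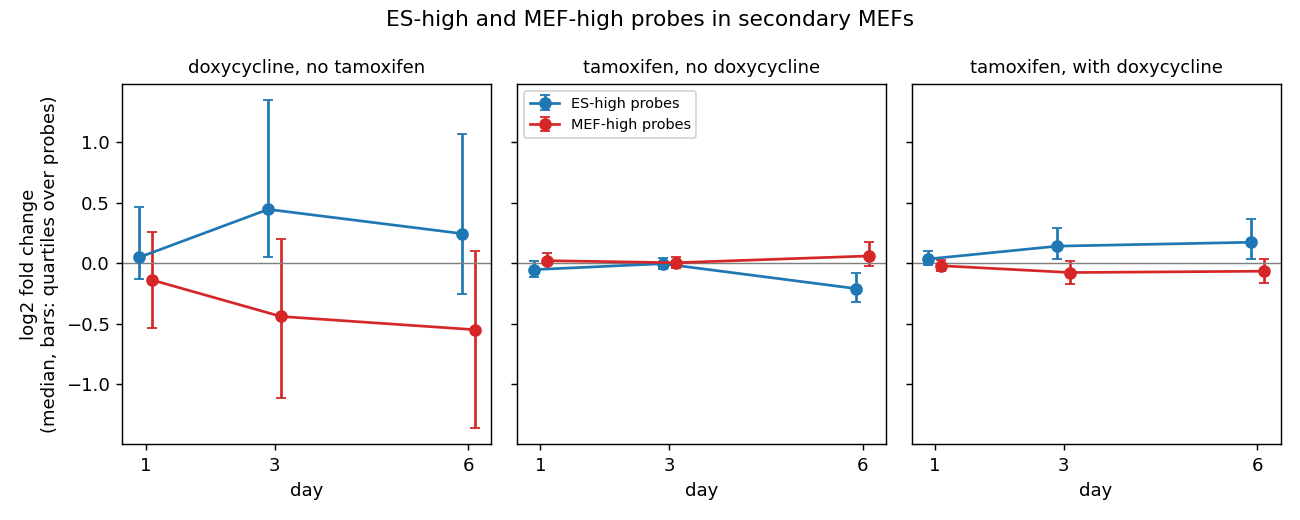
Log2 fold change (y axis) of ES-high (blue) and MEF-high (red) probes in secondary MEFs on days 1, 3 and 6 (x axis), as medians with bars from the lower to the upper quartile over probes, each comparison being 2 arrays against 2. With doxycycline the ES-high medians were 0.05, 0.44 and 0.24 and the MEF-high medians -0.14, -0.44 and -0.55; the ES-high median of -0.21 on day 6 with tamoxifen alone became 0.03 once outlying local backgrounds were replaced.

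Tamoxifen without doxycycline had little measurable effect in the secondary MEFs. Limma called 0 probes on days 1 and 3, 1 on day 6 and 0 averaged over days, with 1298, 522, 2528 and 2966 probes at an unadjusted p under 0.05. The 1 probe called, Z00058330-1, was higher by 0.74 on the log2 scale (SE 0.095, adjusted p = 0.00358). With the values of the authors' deposited series matrix the same fit called 49, 6 and 628 probes on the 3 days and 352 on average, and with Feature Extraction's own ratios it called 2 probes on day 3 and 0 on day 6. The count on day 6 was 6 and 850 without replicates 1 and 2 of the untreated cultures and 3554 and 8 without replicates 1 and 2 of those with tamoxifen. The ES-high probes had a median of -0.21 on day 6 (camera adjusted p = 6.27e-12 with a preset and 0.368 with an estimated correlation), and of 0.03 (adjusted p = 0.152 with a preset one) with outlying local backgrounds replaced. The MEF-high probes had 0.059 on that day (7.79e-06 and 0.368), and 0.036 (0.147 with a preset correlation) after the replacement. On day 1 the ES-high median was -0.054 after the replacement (3.48e-06 with a preset and 0.141 with an estimated correlation).

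Beside doxycycline, tamoxifen changed a larger number of transcripts, and more on the later days. Probe Z00029389-1, well above background in ES cells and not in wild MEFs, rose with tamoxifen by 1.38 on day 3 (SE 0.204, adjusted p = 0.000308) and 1.86 on day 6 (adjusted p = 4.36e-06), with a value of 0.18 on day 1 (adjusted p = 1). Its log2 ratio on day 6 was 0.86 ± 0.07 (SD, n = 2) with doxycycline alone and 2.73 ± 0.13 (SD, n = 2) with both drugs. The ES arrays had 0.76 and 0.72 and the iPS arrays 0.03 and 0.13, so with both drugs the probe lay above both cell types. Probe Z00058073-1, higher in ES cells than in wild MEFs by 4.09, rose by 0.76, 1.27 and 1.26 on days 1, 3 and 6. Its log2 ratios were 2.05 and 2.10 on day 6 with both drugs, above the 1.24 and 1.30 of the ES arrays. An early change that shrank with time was that of Z00023304-1, higher by 1.36 on day 1 (SE 0.091, adjusted p = 4.07e-08), 0.64 on day 3 and 0.29 on day 6 (adjusted p = 0.08). Of the falling probes, Z00036206-1 changed by -1.15 on day 6 (SE 0.172, adjusted p = 0.000218), Z00016353-1 by -1.01 on day 6 and Z00029447-1 by -0.82 on day 3. In all, 18 probes rose and 8 fell on day 1, 723 rose and 283 fell on day 3, and 1068 rose and 331 fell on day 6. Changes of at least 2-fold were few, 22 rising and 0 falling probes on day 3 and 62 and 2 on day 6. Days 3 and 6 share no array, and 543 probes were called on both, all 543 in the same direction. Independent lists would share 26.2 in the same direction. The lists are not independent, since both use 1 estimate of the spread per probe, which raises their overlap. Tamoxifen also had the same slide positions on both days.

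**Figure D2:**
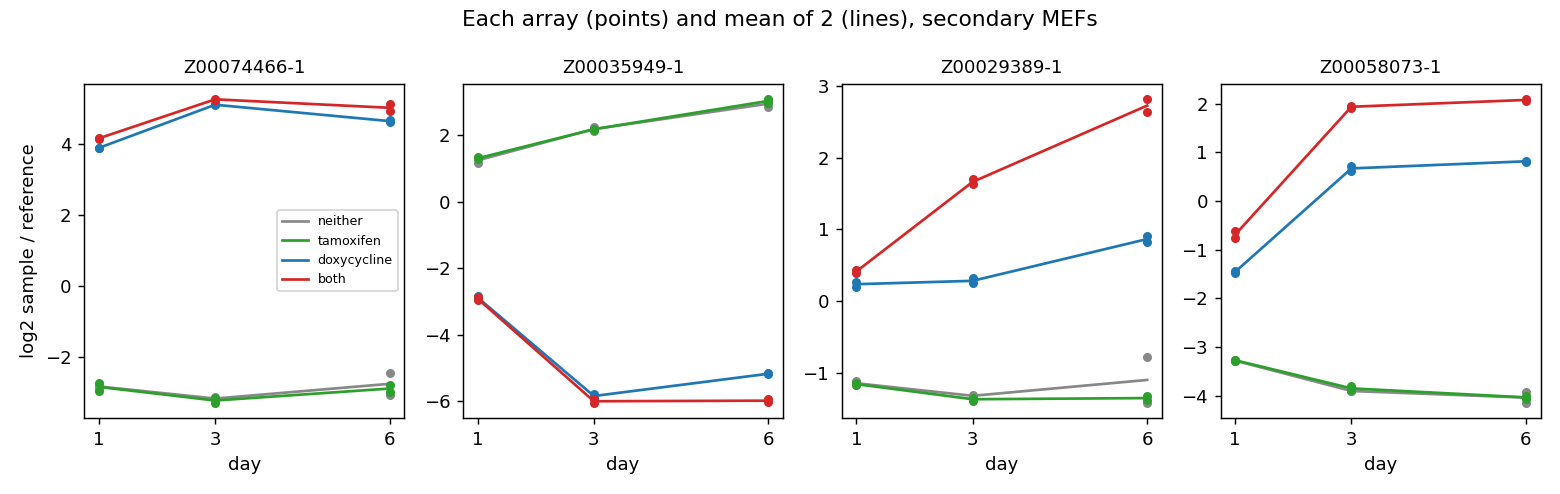
Log2 ratio of sample to reference (y axis) of 4 probes in secondary MEFs by day (x axis), with each array as a point and the mean of 2 arrays as a line, for neither drug (grey), tamoxifen (green), doxycycline (blue) and both (red). Z00074466-1 rose and Z00035949-1 fell with doxycycline, by 7.41 and -8.12 on day 6; Z00029389-1 and Z00058073-1 were higher with both drugs than with doxycycline alone, by 1.86 and 1.26 on day 6.

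As sets, the ES-high probes were shifted upwards and the MEF-high probes downwards by tamoxifen beside doxycycline. In the planned values few members were called, and the set call rests on the preset correlation. Medians of the ES-high probes were 0.03, 0.14 and 0.17 on days 1, 3 and 6, with 2, 60 and 121 of 1194 rising and 1, 2 and 2 falling. Adjusted over the list alone, 3, 82 and 183 rose. Medians of the MEF-high probes were -0.02, -0.08 and -0.07, with 2, 126 and 151 of 2500 falling and 2, 30 and 56 rising. Adjusted over the list alone, 2, 191 and 195 fell. Camera's adjusted p with a preset correlation was 0.00404, 2.05e-10 and 2.86e-12 for ES-high and 0.014, 2.05e-10 and 2.19e-07 for MEF-high probes. With an estimated correlation it was 0.688, 0.407 and 0.361 for both sets, and with the outlying local backgrounds replaced the calls of days 3 and 6 held with an estimated correlation too. After that replacement 36, 352 and 457 of 1201 ES-high probes rose and 2, 14 and 13 fell. Of 2507 MEF-high probes, 9, 299 and 309 fell and 5, 65 and 111 rose. The preset call of day 1 was lost for the ES-high probes without doxycycline replicate 2 (adjusted p = 0.199), and for the MEF-high probes without doxycycline replicate 1 (0.124) or replicate 1 with both drugs (0.172). The arrays with and without tamoxifen of a day shared 1 slide, so each of these comparisons lies within a slide, but tamoxifen always had slide positions 3 and 4. With outlying local backgrounds replaced, 125, 2430 and 3057 probes were called on the 3 days in place of 26, 1006 and 1399, and leaving out any 1 array of a comparison gave 4 to 38, 365 to 455 and 652 to 833.

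The difference between the tamoxifen effects with and without doxycycline was tested as an interaction averaged over days. Probe Z00029389-1 rose by 1.25 more with doxycycline than without (SE 0.166, adjusted p = 0.000129), Z00038074-1 by 1.26 more, and Z00034359-1 and Z00020928-1 had differences of -0.78 and -0.77. The difference was called at 844 probes, 650 upwards and 194 downwards. ES-high probes had a median difference of 0.22, with 87 of 1194 called upwards and 2 downwards, and MEF-high probes one of -0.09, with 96 of 2500 called downwards and 30 upwards (adjusted p = 1.51e-18 and 1.32e-12 with a preset, and 0.255 for both with an estimated correlation). The count was 1484 without replicate 2 of neither drug and 2260 without replicate 1 of tamoxifen alone, both of day 6. With outlying local backgrounds replaced 2163 probes were called. The ES-high median fell to 0.13 with 385 of 1201 called upwards, and the MEF-high median was -0.07 with 299 of 2507 called downwards. The 2 sets then had adjusted p = 0.000201 and 0.0129 with an estimated correlation. With slide as a random block, 71 probes were called for the interaction and 1220 in place of 2303 for tamoxifen beside doxycycline averaged over days. In that fit Z00029389-1 stayed called for the interaction (adjusted p = 0.0439). Z00038074-1, Z00034359-1 and Z00020928-1 did not (adjusted p = 0.126, 0.0821 and 0.107). That fit also took each drug effect as equal on all days, so differences between days enter its error. Both tamoxifen effects lie within slides, so the lower counts cannot be put down to slide.

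In primary MEFs carrying Zscan4ERT2, tamoxifen was accompanied by small changes. Probe Z00030893-1 changed by -1.69 (SE 0.173, adjusted p = 1.18e-05), from a log2 ratio of 3.76 ± 0.07 (SD, n = 2) to 2.08 ± 0.41 (SD, n = 2), and Z00050331-1 by -0.91 (SE 0.057, adjusted p = 1.08e-08). Probes Z00012423-1 and Z00058720-1 were higher by 0.72 and 0.69. As sets, the ES-high and MEF-high probes had medians of 0.015 and -0.006 and were not called (camera adjusted p = 0.45 for both with a preset correlation). In all, 135 probes were called higher and 147 lower. In wild MEFs labelled as treated with tamoxifen, 84 were called higher and 182 lower (15 and 86 with outlying local backgrounds replaced), and the difference between the 2 effects was called at 108 probes, Z00030893-1 among them (-1.57, SE 0.244, adjusted p = 0.00475, but 0.10 with adjusted p = 0.948 in the series matrix). All 3 counts fell to 0 when the fit held only the 8 arrays of primary MEFs, and with outlying local backgrounds replaced they were 1009, 101 and 251. The fit of 8 arrays included a faulty one and had fewer residual degrees of freedom, so its lack of calls decides little. Leaving out 1 array gave 88 to 615 probes in Zscan4ERT2 MEFs, 4 in wild MEFs without untreated replicate 1, 41 without treated replicate 1 and 10919 without treated replicate 2, and 24 to 8164 for the difference. Each of these 4 groups lay on a slide of its own, so slide and group cannot be told apart, and the protocols of the wild MEFs labelled as treated do not mention tamoxifen. The labels also name the Zscan4ERT2 cells MEF2 and the wild cells MEF3, so the 2 may differ in more than the transgene.

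iPS and ES cells, which shared 1 slide, differed at fewer probes than any doxycycline comparison. The doxycycline comparisons lay across slides, so the counts are not alike in that. iPS cells had slide positions 1 and 2 and ES cells 3 and 4, so cell type and position cannot be told apart. The labels also give KOS-ZERT2 for the iPS cells and another line for the ES cells. Line and transgenes therefore cannot be told apart from cell type either. Probe Z00027416-1 was 19.5-fold higher in iPS cells (log2 fold change 4.29, SE 0.077, adjusted p = 8.46e-20) and Z00057363-1 was 6.86-fold higher. Probes Z00059689-1 and Z00006600-1 were 5.36-fold and 4.44-fold lower. Z00027416-1 was also lower in ES cells than in wild MEFs, by -5.25 (SE 0.077, adjusted p = 7.13e-24). It was not high in all MEFs. With outlying local backgrounds replaced, its log2 ratio was -3.76 ± 0.18 (SD, n = 2) in untreated Zscan4ERT2 MEFs, well above background on neither array, and -4.85 ± 0.07 (SD, n = 2) in ES cells. Of 33098 probes, 415 were higher and 894 lower in iPS cells, with 35 and 38 of at least 2-fold. With outlying local backgrounds replaced 2687 probes were called, and leaving out any 1 array gave 612 to 794.

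**Figure D3:**
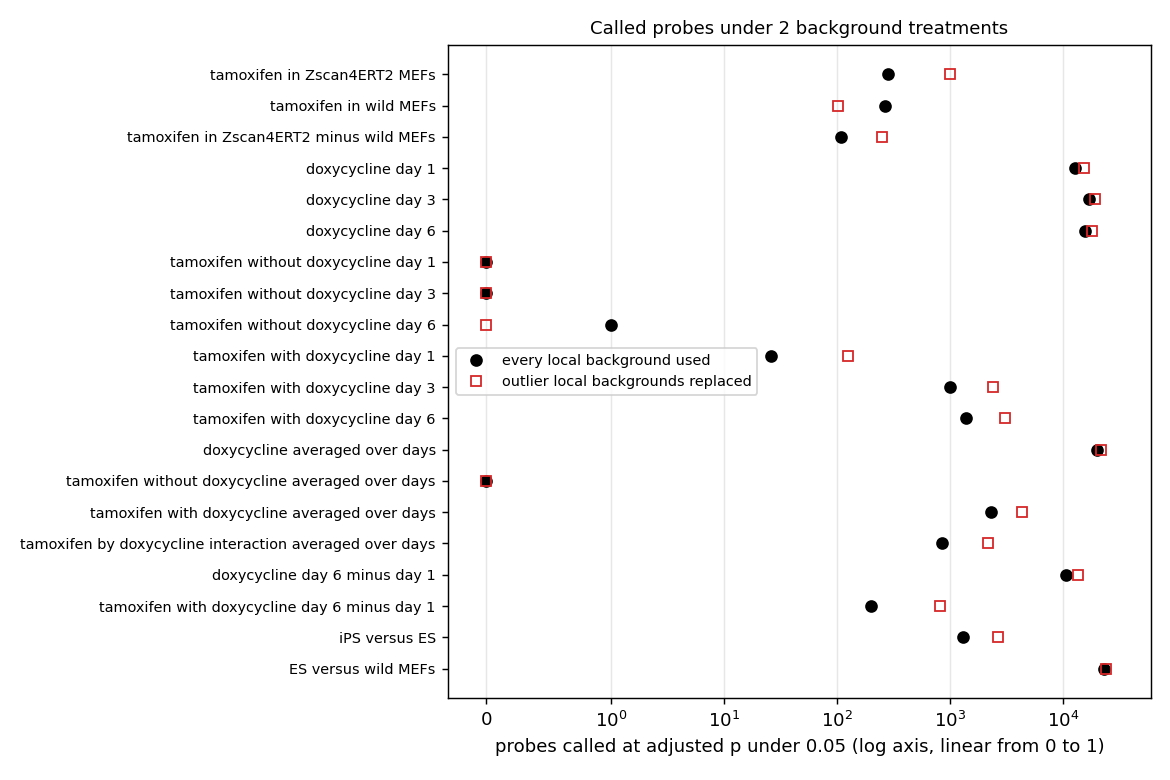
Probes called at an adjusted p under 0.05 (x axis, logarithmic above 1 and linear from 0 to 1) in each comparison (y axis), with every local background used (black circles) and with outlying local backgrounds replaced by the array's median (red squares). The replacement raised tamoxifen beside doxycycline on day 6 from 1399 to 3057 and lowered tamoxifen in wild MEFs from 266 to 101.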

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

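Chosen only after the result was seen were the tests of a tamoxifen response and of the background correction in the first pattern, of slides in the second, and of position and of a larger doxycycline effect in the third, as were both comparisons of day 6 with day 3.

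The effects of a treatment differed between groups or days in 6 tests of the difference itself. The tamoxifen effect differed between Zscan4ERT2 and wild MEFs at 108 probes, and between cultures with and without doxycycline at 844. The doxycycline effect differed between days 6 and 1 at 10629 probes and between days 6 and 3 at 6544. The effect of tamoxifen beside doxycycline differed between days 6 and 1 at 199 probes and between days 6 and 3 at 32. Leaving out 1 array moved the 108 to 8164 (wild MEFs with tamoxifen replicate 2), 24 (untreated wild replicate 1), 50 and 27 (untreated Zscan4ERT2 replicates 1 and 2), 174 and 48 (treated ones). It moved the 844 to 1484 (day 6 with neither drug, replicate 2) and 2260 (day 6 with tamoxifen alone, replicate 1). The 199 became 126 without day 6 replicate 1 of both drugs and 111 and 120 without day 1 replicates 1 and 2 of both, and the 32 became 20 and 15 without doxycycline replicate 2 of day 6 and replicate 1 of day 3.

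The first pattern is in 1 array behind the difference of 108, which was called at 175 probes without the 2 faulty arrays and 251 with outlying local backgrounds replaced: log ratios of wild MEFs with tamoxifen replicate 1 were drawn toward the reference, with a slope of 0.456 against 0.007 in replicate 2. Reference RNA in the sample channel or sample RNA in the reference channel would give slopes above 0.2, and the raw signals gave -0.037 and -0.015; the prediction had not named raw or normalized signals, and the normalized ones, which carry the faulty correction, gave 0.271 and 0.178. ES cell RNA in the sample would leave probes low in both ES cells and MEFs in place, and their median difference was 1.807, while a tamoxifen response shared by replicate 2 would need more than its slope of 0.007; both were measured on the faulty values. With outlying local backgrounds replaced the slope was 0.006, so the compression is consistent with the planned background correction having been fitted to a few spots. The slope was 0.008 with no background subtraction and -0.015 in Feature Extraction's own ratios.

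The second pattern is the 282 probes called with tamoxifen in Zscan4ERT2 MEFs, whose groups lay on separate slides. If slides or scan days had been the whole cause, about 50% of these probes would share their sign with the effect of tamoxifen beside doxycycline on other slides, and 74.8% did, against at most 61.3% over 32 splits of the secondary MEF arrays that hold no treatment difference, 61.3% for the effect in wild MEFs and 64.2% for tamoxifen alone (70.1%, 61.4%, 63.8% and 67.4% with outlying local backgrounds replaced). In wild MEFs without the faulty array, which leaves 1 treated array, the probes moved in the called direction by 6.6% of the change in Zscan4ERT2 MEFs, and with outlying local backgrounds replaced by 5.3% to 18.1% over the pairs of wild arrays; this, which the choice of the probes by their change in Zscan4ERT2 MEFs can lower, is under the 50% that tamoxifen acting without the fusion would need, provided those cells received it, which their protocols do not say. A part contributed by slides stays open, as does a response through the fusion. The count was 0 with only the 8 primary MEF arrays, which include the faulty one and leave fewer residual degrees of freedom.

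The third pattern is the effect of tamoxifen beside doxycycline. Slide positions were the same without doxycycline, where the called probes moved by -0.6% of their change (4.9% without the 2 faulty arrays), which argues against position. The choice of the probes by their change beside doxycycline can lower this share. If tamoxifen only enlarged the doxycycline effect, over 90% of the probes called on day 3 would have the sign of the doxycycline effect of day 6. The doxycycline effect itself kept its sign from day 3 to day 6 at 90.3% of its probes called on day 3, so the limit left almost no room. The share was 70.7%, below that baseline too, which argues against enlargement as the only cause for those probes. The probes behind the 2 shares were not matched in the size of their doxycycline effect. Of the probes called on day 6, 83.8% had the sign of the doxycycline effect of day 3, which leaves it open for them. No biological explanation was tested, and a difference between slides in the cultures compared by the interaction stays open.

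Splits of the arrays within days bear on the averaged comparisons, fitted on probes measured on every array. Of 100 splits, the real one included, 1 gave as many probes as doxycycline (19957, highest other 15694). Again 1 gave as many as tamoxifen beside doxycycline (2299, highest other 1553), so random splits seldom reach either count. The real split also separates slides for doxycycline and slide positions for tamoxifen. Likeness of arrays by slide, position or culture could put it on top, and the splits cannot exclude that. For the interaction 2 of 100 did, and the highest other split called 1051 probes against 842 for the real one. That share is under the limit set beforehand. A split with more calls than the real one points to structure among the arrays, so chance is not excluded there. For tamoxifen without doxycycline the real count was 0 (highest other 1), which all 100 splits reach whatever the data, so the splits decide nothing there.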

How the results depend on the processing

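The fits without the 2 faulty arrays, with outlying local backgrounds replaced and with normexp by maximum likelihood were chosen only after the data were seen, as were both comparisons of day 6 with day 3. No filter on dim probes and normexp by maximum likelihood moved none of the 22 counts by over 1.5 times, and the counts for doxycycline on each day and for ES cells against wild MEFs moved by less than that in every alternative run. Where counts moved, the cause was not tested, except that the replaced backgrounds change only local backgrounds marked as outliers. Signal over background limits dim probes, since as few as 54.9% of probes were well above background on an array.

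Replicate numbers did not consistently pair the samples: over 153 pairs of groups the correlation of deviations ran from -0.63 to 0.73, above 0.1 in 34 and under -0.1 in 36. Between the groups compared for tamoxifen with doxycycline it was 0.03, -0.26 and 0.53 on days 1, 3 and 6. The replicate block moved no count by over 1.5 times and gave, for example, 849 probes for the interaction. That block is 1 offset shared by all groups, so it does not test pairing within a day.

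For tamoxifen in Zscan4ERT2 MEFs, in wild MEFs and their difference (282, 266 and 108 probes), no background subtraction gave 3393, 111 and 693, Feature Extraction's ratios 1553, 843 and 1132, the series matrix 1893, 1043 and 1455, the fit without the 2 faulty arrays 917, 59 and 175, replaced backgrounds 1009, 101 and 251, and only the 8 primary MEF arrays 0, 0 and 0. The 8 primary MEF arrays include a faulty one and leave fewer residual degrees of freedom. For tamoxifen without doxycycline (0, 0 and 1 on days 1, 3 and 6, and 0 on average), the series matrix gave 49, 6, 628 and 352. On day 6 it was 2 with no background subtraction, 0 with Feature Extraction's ratios (2 on day 3), 0 with replaced backgrounds, and 8 without the 2 faulty arrays (2 on average).

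For tamoxifen with doxycycline on days 1, 3 and 6 and on average (26, 1006, 1399 and 2303), no background subtraction gave 151, 2781, 3427 and 4904, the series matrix 139, 2056, 2422 and 3587, the fit without the 2 faulty arrays 95, 2338, 2992 and 4282, and replaced backgrounds 125, 2430, 3057 and 4378. Feature Extraction's ratios gave 69 and 1552 on days 1 and 3. For the interaction and for iPS against ES cells (844 and 1309), the same 5 alternatives gave 2506 and 3008, 1927 and 2627, 1861 and 2629, 2163 and 2687, and 1295 and 2711, and only the arrays of the same experiment 1616 and 2853. For the change of the tamoxifen effect with doxycycline from day 1 to 6 and from day 3 to 6 (199 and 32), they gave 933 and 211, 607 and 239, 773 and 134, 812 and 160, and 343 and 53, and only the arrays of the same experiment 320 for the first. With slide as a random block, counts were 12053 for doxycycline averaged over days, 1220 for tamoxifen with doxycycline averaged over days and 71 for the interaction. That fit took each drug effect as equal on all days, so more than the slide block set it apart.

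Camera was not run with the replicate block or with slide as a random block. In the other alternatives the preset calls held except in 3 fits that left out an array. With an estimated correlation, adjusted p was 0.726, 0.438 and 0.549 for ES-high and 0.726, 0.429 and 0.246 for MEF-high probes with doxycycline on days 1, 3 and 6, 0.688, 0.407 and 0.361 for both sets with tamoxifen beside it, and 0.255 for both in the interaction. Without the 2 faulty arrays 3 calls were still lost, at 0.274 for both sets with doxycycline and 0.308 for MEF-high probes with tamoxifen beside it, all on day 1. With replaced backgrounds 4 were, at 0.274 for both sets with doxycycline and 0.0688 and 0.271 for ES-high and MEF-high probes with tamoxifen beside it, also on day 1. Probe Z00024687-1 changed sign for tamoxifen with doxycycline on day 1 with Feature Extraction's ratios (0.17), and Z00030893-1 for the difference between Zscan4ERT2 and wild MEFs in the series matrix (0.1).

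Leaving out 1 array of the compared groups, with the lone array taken to vary like the other groups, gave ranges of 88 to 615 for tamoxifen in Zscan4ERT2 MEFs, 4 to 10919 in wild MEFs and 24 to 8164 for their difference. In Zscan4ERT2 MEFs each array mattered, with 124 and 88 without untreated replicates 1 and 2 and 615 and 89 without treated replicates 1 and 2. In wild MEFs it was 4 without untreated replicate 1, 41 without treated replicate 1 and 10919 without treated replicate 2, which leaves the faulty array alone. The difference was 50, 27, 174 and 48 without those Zscan4ERT2 arrays in the same order, 24 without wild untreated replicate 1 and 8164 without wild treated replicate 2.

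For tamoxifen without doxycycline the ranges were 0 to 8 on day 1, 0 to 14 on day 3, 6 to 3554 on day 6 and 0 to 2177 on average. On day 6 the counts were 6 and 850 without replicates 1 and 2 of neither drug and 3554 and 8 without replicates 1 and 2 of tamoxifen alone, which gave 2, 61, 2177 and 4 on average; replicate 2 of neither drug on day 3 gave 14 on that day and 7 on average, and replicate 1 gave 3. On day 1 it was 8 without replicate 1 of neither drug and 1 without replicate 2 of tamoxifen alone. For the interaction the range was 621 to 2260, with 1484 without replicate 2 of neither drug and 2260 without replicate 1 of tamoxifen alone on day 6.

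For tamoxifen with doxycycline the ranges were 4 to 38 on day 1, 365 to 455 on day 3 and 652 to 833 on day 6. Without replicates 1 and 2 of doxycycline alone and 1 and 2 of both drugs, in that order, day 3 gave 374, 455, 365 and 451 and day 6 gave 756, 652, 664 and 833. Day 1 gave 12 without replicate 1 of doxycycline alone and 4 and 9 without replicates 1 and 2 of both drugs. On that day the ES-high adjusted p ran from 0.000184 to 0.199, the latter without replicate 2 of doxycycline alone, and the MEF-high one from 0.00902 to 0.172, with 0.124 without replicate 1 of doxycycline alone and 0.172 without replicate 1 of both drugs. The change from day 1 to 6 ran from 111 to 173, with 126 without replicate 1 of both drugs on day 6 and 111 and 120 without replicates 1 and 2 of both drugs on day 1. The change from day 3 to 6 ran from 15 to 38, with 20 without replicate 2 of doxycycline alone on day 6 and 15 without replicate 1 of it on day 3. iPS against ES cells ran from 612 to 794, with 688 and 706 without iPS replicates 1 and 2 and 794 and 612 without ES replicates 1 and 2.

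In the other leave-one-out fits no count moved by over 1.5 times. Doxycycline gave 9958 to 11868 probes on day 1, 14870 to 14902 on day 3, 13416 to 14492 on day 6 and 18962 to 19706 on average, and its change 8862 to 10258 from day 1 to 6 and 4905 to 7038 from day 3 to 6. ES cells against wild MEFs gave 21704 to 21960, and tamoxifen with doxycycline on average 1601 to 1924. For ES-high and MEF-high probes adjusted p ran from 0.00284 to 0.0239 and 0.00179 to 0.017 with doxycycline on day 1, 3.86e-09 to 5.2e-09 and 5.38e-10 to 1.57e-09 on day 3, and 7.82e-10 to 0.00283 and 3.17e-17 to 6.63e-12 on day 6. With tamoxifen beside it they ran from 4.45e-10 to 1.78e-08 and 1.9e-09 to 1.4e-08 on day 3 and from 6.73e-12 to 9.52e-09 and 2.61e-09 to 0.000435 on day 6, and in the interaction from 4.29e-24 to 2.08e-12 and 1.05e-13 to 1.11e-09.

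Single probes kept their direction but lost their call in 19 cases with Feature Extraction's ratios, 15 with only the arrays of the same experiment, 6 with no filter, 5 each with no background subtraction, replaced backgrounds and the series matrix, 4 without the 2 faulty arrays, 3 with slide as a block, 2 with the replicate block and 76 when leaving out an array.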

Other observations

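Every set test in this part was chosen only after the result was seen.

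A set of 1546 probes not well above background in ES cells, iPS cells or primary MEFs was also tested. Such probes pass the filter on dim probes through secondary MEFs alone, which favours those that a treatment raises, so the test of a rise decides nothing and no value is given.

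As a set, probes that fell with tamoxifen in primary Zscan4ERT2 MEFs were shifted downwards by tamoxifen beside doxycycline in the secondary MEFs, on other slides, where 60 of the 147 were called lower and 10 higher. The hypothesis was that a shared response to the fusion lowers them. Camera with an estimated correlation gave adjusted p = 6.85e-06 for the effect averaged over days, with medians of -0.10, -0.14 and -0.08 on days 1, 3 and 6. With tamoxifen alone, where a response to the fusion by itself would also be seen, their median was -0.02 (adjusted p = 0.165 with an estimated and 0.003 with a preset correlation), and on day 6 the 472 such probes found with outlying local backgrounds replaced had one of -0.03 (adjusted p = 0.0116 with an estimated correlation). The difference between the effects with and without doxycycline was called (adjusted p = 0.000557). The fall was therefore larger beside doxycycline, and a response to the fusion by itself stays open. Of the 147 probes, 45 were MEF-high, while MEF-high probes were 7.6% of all probes tested. MEF-high probes also fell with tamoxifen beside doxycycline, with 279 called lower and 75 higher averaged over days. How much of the repeated fall comes from this membership was not tested. For the 135 probes that rose in primary MEFs the adjusted p in the same test was 0.0948 averaged over days. Their medians on days 1, 3 and 6 were 0.064, 0.033 and 0.065, with adjusted p = 0.0388, 0.482 and 0.122. Only day 1 was called, so whether they rise again on all days cannot be decided with this test. Across the 2 comparisons, which share no array, 104 probes were called in both and 91 of them in the same direction. Independent lists would share 9.6 in the same direction, but both lists use 1 estimate of the spread per probe, which raises their overlap.

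The ES-high probes were lower on day 6 than on day 3 of doxycycline by a median of -0.26 (adjusted p = 0.0143 with a preset and 0.75 with an estimated correlation), but with outlying local backgrounds replaced the median was -0.04 (adjusted p = 0.942 with a preset correlation), so no drop is claimed. The 2 arrays of secondary MEFs with tamoxifen alone on day 6 differed from each other with an SD of 0.255 over probes, against a median of 0.116 over groups, and of 0.256 after the replacement of local backgrounds; the cause was not tested.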
